A study of Homo sapiens with 12 samples.

How the data were processed

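Nuclei from frozen post-mortem prefrontal cortex of 6 donors with Parkinson's disease (PD) and 6 control donors were profiled by single-nucleus RNA sequencing, with 1 library per donor. Per the labels' protocols, nuclei were purified by ultracentrifugation through sucrose, and libraries were made with the 10x Genomics Chromium 3′ kit, version 3, and sequenced on an Illumina NovaSeq instrument. In this droplet method each captured RNA molecule carries a unique molecular identifier (UMI), so that copies made by PCR are counted once. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 3.1.0 per the file headers. The genome build was GRCh38 per the submitters' processing notes; the annotation version, and whether intronic reads were counted, are not given in the sources used here. Libraries held 12450049 to 93464497 UMIs. Every deposited barcode held at least 500 UMIs, and no table of cell types was used. Each file lists 33538 genes, of which 33456 identifiers were found in the GENCODE v29 annotation that supplied the coordinates given here. XIST, TSIX and the Y-linked genes (102 in all) were left out of the variable genes and of the summed counts. They were still counted in the UMIs and genes per nucleus and in the doublet scores.

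Barcodes with at least 500 detected genes and at most 5% mitochondrial UMIs were kept, which removed 1696 of 77983. Doublets were scored per library against simulated doublets by the Scrublet approach, as re-implemented for these data, and the top-scoring nuclei were removed at 0.8% per 1000 barcodes. That rate was set in advance, not estimated, and took 4493 nuclei (5.76% of the barcodes). The remaining 71794 nuclei were log-normalised and reduced to 40 principal components of 3000 variable genes (scanpy 1.11.5). Libraries were aligned with a re-implemented Harmony correction, which was chosen after un-integrated clusters had been seen and before any comparison of diagnoses. Leiden clustering (leidenalg 0.10.2, resolution 1, 20 neighbours) gave 35 clusters. A cluster took the name of a class only from marker genes fixed before the data were examined, with at least 3 of them at least 2-fold above the other clusters and seen in at least 10% of its nuclei, and with no other class holding more markers among its top 10 genes. All 35 clusters could be named under 8 classes. Neurons were clustered again within the excitatory and inhibitory classes for 7 subclasses; subclusters with more markers of another class than of their own subclass among their top 10 genes stayed unnamed, a rule set after the subclusters had been seen.

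Nuclei are not replicates, so UMI counts were summed per library and class, and the sums were compared between the 6 PD and 6 control libraries. A library entered with at least 20 nuclei of the class, and a class was tested with at least 4 such libraries per group, which left out T cell-like nuclei and gave 5 against 5 libraries for vascular-like nuclei. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F test) with Benjamini-Hochberg adjustment within a class at 0.05. No covariate was used, because the sources used here give none for a donor. The gene lists (29) and class marker lists (8) were fixed before the data were examined and tested with limma 3.58.1 camera on voom values at a preset inter-gene correlation of 0.01, adjusted over all 229 list-by-class tests with at least 5 tested members. The same test with an estimated correlation, and fry, were run beside it. The marker lists of a class were tested in the other classes, as a check for RNA or nuclei of other types. List medians are medians of the members' log2 fold changes (PD over control) on the voom scale, and gene fold changes are those of edgeR, with a standard error (SE) taken from the fold change and its F statistic. Levels are CPM, the UMIs of a gene scaled to the library total of the class, as mean ± SD over libraries. For single genes that total covers the genes passing the filter and is adjusted by TMM. Summed list levels use the plain total. A gene given as higher or lower in some of the PD libraries lay above or below the control median in them, not beyond each control. Shares of nuclei, quality measures and summed list levels were compared with two-sided exact permutation tests over the 924 assignments of the 12 libraries, whose smallest p is 0.00216. Correlations of fold changes between classes were set beside 100 splits of the donors, the real one counted among them, as were the counts of called genes and lists.

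The genes named in the text follow a rule fixed in advance. For each class it takes the 5 largest rises and 5 largest falls among genes past the threshold that moved the same way in at least 5 PD donors; where fewer than 5 pass, it takes those that pass and the 4 of smallest unadjusted p. Clone-based symbols were excluded by that rule, also in the choice by smallest p. The rule adds 4 members of smallest p of each called list and 8 PD genes, each in the class of its highest mean CPM, and any member of the PD gene list past the threshold. Because 70 lists were called, members are named for the 4 lists of smallest p per class, a number set after the results were seen. Some genes that this rule names are not reported here. Genes called by other tools alone are named as chosen after their values were seen.

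Alternatives fixed in advance were DESeq2-type size factors, DESeq2 1.42.0, limma voom, no filter on low counts, a stricter filter on nuclei (1000 genes, 2% mitochondrial UMIs), doublets kept, a class taken from the highest marker score, depth per nucleus as a covariate, the spelling of the library title prefix (capitals or small letters) as a block, 1 surrogate variable (sva 3.50.0), and leaving out each library. A block for a mitochondrial share above 0.5%, and leaving out control 3 and PD 3 together, were added after the data had been seen. The tests were run on simulated counts for the real genes and library sizes with 200 changed genes, each gene being drawn independently of the others. Of genes changed 4-fold, 59.1% to 86.4% were recovered depending on the class, against 2.99% to 38.8% at 2-fold and 0 to 5.97% at 1.5-fold. Replicate numbers only name the libraries and pair none of them, since every donor is a different person. In each class of neurons and glia, the summed counts of each pair of libraries differed by more than sampling noise (chi-square per degree of freedom at least 3.16), so no library was counted as a repeat of another. The analysis ran under Python 3.11.15 and R 4.3.3.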

Results

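The comparison asks which cell classes and genes of the prefrontal cortex differ between donors with PD and controls. Of 77983 barcodes, 71794 nuclei were kept. They fell into excitatory neuron-like (19569 nuclei), inhibitory neuron-like (11640), oligodendrocyte-like (22574), oligodendrocyte precursor (OPC)-like (4824), astrocyte-like (7549), microglia-like (4903), vascular-like (475) and T cell-like (260) classes. Kept nuclei per library ran from 1765 in PD 3 to 9424 in PD 4, and median UMIs per nucleus from 3856 in PD 4 to 9014 in PD 5.

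Library quality did not differ detectably between the groups. PD and control libraries held 6470 ± 2744 and 5496 ± 886 kept nuclei (mean ± SD, n = 6 each; difference 974, two-sided exact permutation p = 0.435). Median UMIs per nucleus were 5571 ± 1933 and 5856 ± 1284 (difference -286, exact p = 0.749), and median genes 2514 ± 496 and 2652 ± 325 (difference -138, exact p = 0.578). The mitochondrial share of UMIs was 0.549 ± 0.378% and 0.544 ± 0.208% (exact p = 0.961), and the adjusted p was 0.961 for each of the 4 measures. Without PD 3, the smallest library, the difference in kept nuclei was 1915 (exact p = 0.0433). The difference in median UMIs turned to 167, 46.6 and 57.3 without control 1, PD 3 and PD 4. That in mitochondrial share, 0.00469 percentage points, turned to -0.0284, -0.0337, -0.0348, -0.0448 and -0.128 without control 2, control 3, control 4, PD 5 and PD 6.

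Microglia-like nuclei made up 8.49 ± 5.33% of the nuclei in PD libraries against 4.79 ± 2.08% in controls, and all 6 PD libraries lay above the control median (difference 3.70 percentage points, exact permutation p = 0.0801, adjusted p = 0.433 over 8 classes). T cell-like nuclei made up 0.551 ± 0.702% against 0.119 ± 0.0623%, with 5 PD libraries above the control median and 3 above the highest control (difference 0.432, exact p = 0.108, adjusted p = 0.433). Neither difference passed the threshold, and PD 1 carried much of both: it held 19.1% microglia-like nuclei, against 8.05% in the next PD library, and 142 of the 260 T cell-like nuclei. Without PD 1 the differences were 1.57 for microglia-like and 0.169 for T cell-like nuclei.

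The differences of the other classes had larger exact p values. Excitatory neuron-like nuclei were 31.1 ± 9.44% in PD against 25.8 ± 10.5% (exact p = 0.372), and inhibitory neuron-like nuclei 16.1 ± 3.35% against 16.6 ± 4.43% (exact p = 0.788). Oligodendrocyte-like nuclei were 28.4 ± 13.1% against 32.9 ± 11.03% (exact p = 0.519), and OPC-like nuclei 6.12 ± 1.57% against 7.23 ± 1.88% (exact p = 0.286). Astrocyte-like nuclei were 8.53 ± 3.62% against 11.9 ± 6.88% (exact p = 0.325) and vascular-like nuclei 0.704 ± 0.258% against 0.622 ± 0.262% (exact p = 0.587). Their adjusted p lay between 0.596 and 0.788, and the inhibitory difference of -0.533 turned to 1.23 without control 2 and 0.317 without PD 4. It was -1.70, -0.153, -1.13, -1.06 and -0.915 without PD 1, PD 6, control 3, control 5 and control 6. The oligodendrocyte difference of -4.52 was -1.58, -9.20, -2.84, -7.99, -2.60 and -2.41 without PD 1, PD 4, PD 5, control 1, control 3 and control 6. The excitatory difference of 5.30 was 8.82, 8.95 and 3.24 without PD 4, control 1 and control 6, and the astrocyte difference of -3.34 was -5.23 and -1.33 without control 2 and control 4. The OPC difference of -1.12 was -0.561 without PD 3, and the vascular difference of 0.0828 was 0.168, 0.0454, 0.0195, 0.00946 and 0.168 without PD 2, PD 4, PD 6, control 2 and control 4. The library titles use 2 spellings of their prefix, which split the libraries 2 against 2 (capitals; smallest possible exact p 0.333) and 4 against 4 (small letters). Microglia-like nuclei differed by -0.872 within the first and 5.99 within the second (exact p = 0.0571, adjusted p = 0.229), and T cell-like nuclei by -0.0304 and 0.664 (exact p = 0.0571, adjusted p = 0.229). The remaining differences within the capitals and small letters were 6.24 and 4.83 for excitatory neurons, and 1.38 and -1.49 for inhibitory neurons. They were -6.88 and -3.35 for oligodendrocytes, -0.727 and -1.31 for OPCs, 1.07 and -5.55 for astrocytes, and -0.1797 and 0.214 for vascular nuclei.

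**Figure D1:**
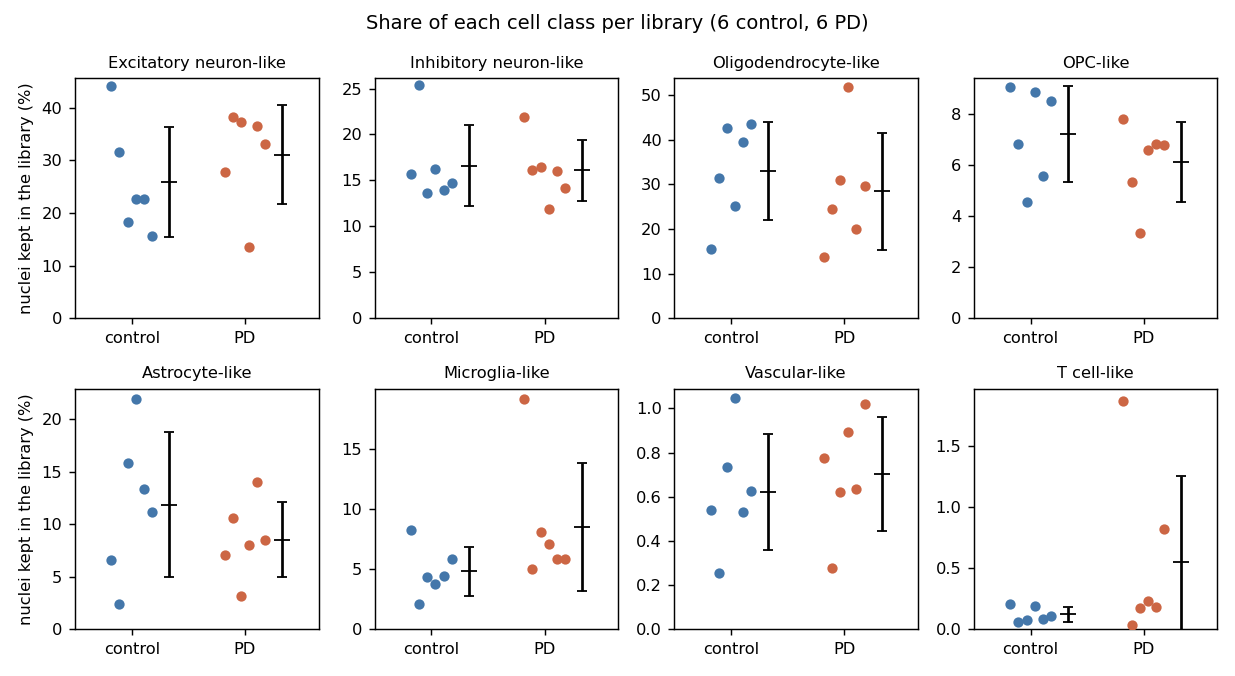
Share of each cell class (percent of the kept nuclei of a library) in control and PD libraries, with a point per library and the group mean ± SD at the right of each group; the SD bar of PD T cell-like nuclei ends at 0. The highest PD microglia-like share is 19.1% (PD 1), and the group means are 8.49% and 4.79%.

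No difference in the shares of neuron subclasses was detected. Of the excitatory nuclei, upper-layer nuclei were 25.5 ± 11.1% in PD and 26.6 ± 7.97% in controls, middle-layer nuclei 20.5 ± 10.7% and 20.4 ± 7.199%, and deep-layer nuclei 14.6 ± 17.6% and 13.3 ± 6.596%. Of the inhibitory nuclei, PVALB nuclei were 17.9 ± 5.73% and 15.8 ± 6.44%, SST nuclei 14.9 ± 7.22% and 12.9 ± 4.38%, VIP nuclei 19.1 ± 5.65% and 21.3 ± 4.70%, and LAMP5 nuclei 14.0 ± 2.37% and 15.3 ± 2.74%. The smallest exact permutation p was 0.366 (LAMP5), and the adjusted p was 0.991 for all 7. PD 3 stood apart, with 48.3% deep-layer and 7.74% upper-layer among 659 excitatory nuclei. Without it the PD minus control differences turned from 1.34 to -5.38 for deep-layer, from -1.02 to 2.54 for upper-layer and from 2.03 to -0.432 for SST nuclei. The upper-layer difference also turned without control 2 (1.44) and control 5 (0.109), the deep-layer one without control 2 (-0.476), and the middle-layer one, 0.110, without control 2 (-1.68), control 4 (-1.71), PD 4 (-0.442) and PD 6 (-3.60). No subclass could be named for 41.2% of the excitatory and 35.3% of the inhibitory nuclei.

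No gene passed the threshold in any of the 7 classes tested with edgeR, over 88255 gene-by-class tests, of which 2630 had an unadjusted p under 0.05. Limma voom called 0 genes and DESeq2 called 20. In simulated data with the real library sizes and spread, the tests recovered 59.1% to 86.4% of genes changed 4-fold and 0 to 5.97% of those changed 1.5-fold. The values of single genes below are those of smallest unadjusted p and did not pass. Of the 229 tests of gene lists, camera called 70 at its preset correlation, 57 higher and 13 lower in PD. None of these calls held with an estimated correlation (smallest adjusted p = 0.717, 10 tests at an unadjusted p under 0.05, median estimated correlation 0.352) or with fry (smallest adjusted p = 0.982, 9 at an unadjusted p under 0.05; for change in either direction 0.986). A member passed the threshold adjusted over the list alone in 8 of the called lists and over all genes in 0. Of the 70 calls, 53 ended when at least 1 library was left out. The direction of the camera test turned in 6, and the list median changed sign in 13.

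In astrocyte-like nuclei, 20 of 34 lists were called, 17 higher in PD. Immediate early genes, which neurons and glia switch on within minutes of a stimulus, had a median log2 fold change of 0.87 (20 members, 19 higher, camera adjusted p = 1.33e-05, and adjusted p = 0.717 with an estimated correlation). DUSP1 was at 39.2 ± 26.7 CPM in PD against 6.36 ± 2.78 in controls (log2 fold change 2.49 ± 0.56 SE, higher than the control median in 5 of 6 PD libraries). FOS (2.55 ± 0.75) was higher in 6 of 6, and NR4A1 (5.15 ± 1.35) and NR4A3 (4.70 ± 1.35) in 5 of 6. Much of the NR4A1 and NR4A3 folds came from PD 3: without it they were 2.84 and 1.88, and with depth per nucleus as a covariate 0.74 and 0.23. DUSP1 and NR4A1 were the 2 genes DESeq2 called here (DUSP1: DESeq2 adjusted p = 0.0355, and 0.0355 to 0.99995 over the alternatives). In this list 9 members passed adjusted over the list alone. The hypoxia response (median 0.51, 25 members, camera adjusted p = 1.33e-05, 0.717 with an estimated correlation) included DDIT4 (1.74 ± 0.46), HK2 (1.96 ± 0.63), ANKRD37 (2.34 ± 0.78) and VEGFA (1.57 ± 0.57), above the control median in 5, 6, 5 and 3 of 6 PD libraries. ANKRD37 was at 1.30 without PD 3 and 0.52 with the depth covariate, and VEGFA at 0.95 without PD 1.

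Also in astrocyte-like nuclei, cytosolic ribosomal proteins (median 0.33, 64 members) had a camera adjusted p of 1.33e-05 (0.841 with an estimated correlation). RPS15, RPL28, RPS9 and RPL10 were at 1.05, 0.69, 1.22 and 0.93. Without PD 3, RPS15, RPS9 and RPL10 were at 0.69, 0.47 and 0.42. With depth per nucleus as a covariate their median was -0.02. Presynaptic vesicle genes (median 0.40, 34 members) had 1.48e-05 (0.717 with an estimated correlation). SYT1, SYP, SYN1 and DNM1 were at 1.18, 0.68, 0.87 and 0.73. Ion channels (median 0.58) and metallothioneins (median 1.14, 8 of 8 members higher) were called too (0.717 for both with an estimated correlation), and these 6 lists kept their calls without each library. The immediate early median was 0.55 without PD 6, the hypoxia median 0.28 without PD 1, and the ribosomal median 0.19, 0.16 and 0.58 without PD 3, PD 4 and PD 5. The remaining 14 calls ended without at least 1 library. Homeostatic astrocyte genes (median -0.37, camera adjusted p = 0.00696, 0.841 with an estimated correlation) were at -0.05 without PD 3 (adjusted p = 0.649) and at 0.15 with the depth covariate, and heat shock genes (median 0.37, 0.839 with an estimated correlation) at 0.11 without PD 3 (adjusted p = 0.0710). Reactive astrocyte genes (median 0.24, camera adjusted p = 0.0477, 0.859 with an estimated correlation) lost the call without 7 of the 12 libraries and were at -0.23 without PD 1. The astrocyte-like class pools a cluster of 5585 nuclei (44.4% from PD libraries) with GJA1 and AQP4 among its top genes, and a cluster of 1964 (56.4%) with GFAP and CD44. The median UMIs of their nuclei were 0.983 and 0.317 times those of the library. For the lists of this class, a difference in that mix was not tested apart from a change within either cluster. Of the 13255 genes tested, 537 had an unadjusted p under 0.05 (398 higher, 139 lower; 663 would by chance), 859 without PD 5. Besides DUSP1, those of smallest p were RUNX1 (1.25 ± 0.29), which is in the microglia marker list, FGF17 (1.80 ± 0.43) and ATRNL1 (1.56 ± 0.37).

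In microglia-like nuclei, 14 of 32 lists were called, 13 higher in PD. Heat shock proteins and chaperones had a median of 0.44 (34 members, 31 higher, camera adjusted p = 4.72e-09, 0.717 with an estimated correlation). Among them, HSP90AB1 (0.92 ± 0.25), STIP1 (0.98 ± 0.28) and HSPB1 (1.49 ± 0.50) were higher in 6 of 6 PD libraries, and DNAJB1 was at 2.53 ± 0.81. Immediate early genes had a median of 0.98 (16 members, camera adjusted p = 1.48e-05, 0.717 with an estimated correlation). BTG2 (1.44 ± 0.40) and JUNB (2.51 ± 0.75) were higher in 6 of 6, with JUND at 1.51 and DUSP1 at 2.36. Without PD 3, JUNB, JUND and DUSP1 were at 1.16, 0.63 and 1.40. There, 2 members passed adjusted over the list alone. Postsynaptic glutamatergic genes (median 0.73, 20 of 20 members higher) had a camera adjusted p of 1.33e-05 (0.717 with an estimated correlation). CAMK2B, HOMER1, CAMK2A and DLGAP2 were at 1.09, 3.02, 1.14 and 1.19. CAMK2B and CAMK2A were at 0.58 and 0.52 without PD 5, and DLGAP2 at 0.74 without PD 2. The hypoxia response (median 0.65, 19 members) had 1.48e-05 (0.717 with an estimated correlation). ANKRD37, PGK1, VEGFA and ENO1 were at 1.90, 0.97, 2.06 and 0.85. VEGFA was at 1.19 without PD 3. These 4 lists kept their calls without each library, with medians of 0.42 without PD 5 (postsynaptic), 0.43 and 0.40 without PD 1 and PD 6 (hypoxia) and 0.59 without PD 3 (immediate early). HOMER1 was at -0.26 without PD 3.

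The other 10 calls in microglia-like nuclei ended without at least 1 library. Homeostatic microglia genes lay lower (median -0.39, camera adjusted p = 0.0108, 0.839 with an estimated correlation; -0.26 and adjusted p = 0.124 without PD 3), and NF-kB and cytokine genes higher (median 0.59, camera adjusted p = 0.00750, 0.761 with an estimated correlation; adjusted p = 0.135 without control 1 and 0.145 without PD 3). SNHG15, a noncoding host gene of small nucleolar RNAs, was at 79.3 ± 46.3 CPM in PD against 19.7 ± 6.80 (log2 fold change 1.96 ± 0.39 SE, edgeR adjusted p = 0.836, higher in 6 of 6). It was the 1 gene DESeq2 called (adjusted p = 0.0204; 0.0204 to 0.960 over the alternatives). FBXO8 (-1.24 ± 0.29), SH2B2 (1.71 ± 0.40) and TMEM59L (1.08 ± 0.26) came next. Of 9401 genes, 528 had an unadjusted p under 0.05 (347 higher, 181 lower; 470 by chance), 340 without control 6. Without PD 4, edgeR called LINC00649, lower in PD (adjusted p = 0.0373).

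In oligodendrocyte-like nuclei, ATP6V0D2, a subunit of the vacuolar proton pump, was at 13.8 ± 10.1 CPM in PD against 1.63 ± 1.02 (log2 fold change 3.00 ± 0.52 SE, higher in 6 of 6). Its edgeR adjusted p was 0.570. It was the 1 gene of the class that DESeq2 called (adjusted p = 7.22e-05; 7.22e-05 to 0.9999 over the alternatives). HSPA1B (3.17 ± 0.84), ANKRD37 (1.49 ± 0.40) and KCNJ14 (1.29 ± 0.33) came next. Reads of HSPA1B and HSPA1A, HLA genes, MT1 genes and ribosomal protein genes with near-identical copies cannot be assigned with certainty. Of 14705 genes, 455 had an unadjusted p under 0.05 (284 higher, 171 lower; 735 by chance), 770 without PD 5 and 733 without PD 6. Of 34 lists, 6 were called. Microglia markers had a median of 0.80 (8 members, camera adjusted p = 0.000393, 0.717 with an estimated correlation), and 3 passed adjusted over the list alone. RUNX1, CD74, DOCK8 and C3 were at 1.05, 1.34, 1.14 and 1.18. Without PD 1, CD74 and C3 were at 0.83 and 0.64. The call held without each library, with medians of 0.47, 0.42 and 0.47 without control 2, control 4 and PD 4. Marker lists serve as a check for RNA or nuclei of other classes. Microglial RNA or nuclei were not tested apart from a change within oligodendrocytes. Cholesterol synthesis lay lower (median -0.28, 23 members, camera adjusted p = 0.00198, 0.841 with an estimated correlation). STARD4, MSMO1, SC5D and HSD17B7 were at -0.65, -0.74, -0.49 and -0.46. Without control 5, MSMO1, SC5D and HSD17B7 were at -0.38, -0.27 and -0.23. SC5D was at -0.29 without control 3, and HSD17B7 at -0.31 without PD 3. The cholesterol median was -0.19 without PD 1 (adjusted p = 0.0673) and -0.11 without control 5 (adjusted p = 0.352).

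Ribosomal protein genes (median 0.14, 65 members) and ion channels (median 0.28, 26 members) were called higher in oligodendrocyte-like nuclei (camera adjusted p = 0.00580 and 0.00839, 0.859 and 0.841 with an estimated correlation). RPLP2, RPL7, RPL10 and RPS28 were at 0.84, 0.71, 0.50 and 0.86. SCN3A, KCNH7, KCND2 and SCN2A were at 0.90, 0.63, 0.80 and 0.66. KCND2 and SCN2A were higher in 3 of 6 PD libraries, and at 0.27 and 0.18 without PD 5. The ribosomal call ended without control 3 (0.07, adjusted p = 0.274), control 4 (0.04, 0.343), PD 3 (0.05, 0.213) and PD 6 (0.02, 0.921), and its median was 0.22 and 0.28 without PD 4 and PD 5. RPLP2, RPL7, RPL10 and RPS28 were at 0.21, 0.20, 0.30 and -0.04 without PD 3. The channel call ended without PD 1 (0.22, adjusted p = 0.0847), PD 5 (0.07, 0.729) and control 5 (0.22, 0.185), and its median was 0.42, 0.51 and 0.45 without control 3, PD 4 and PD 6. Neuron-enriched genes outside the lists had a median of 0.37 in these nuclei, against 0.35 for members of the synaptic and channel lists and 0.03 for other genes.

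In OPC-like nuclei, the glycolytic gene GPI was at 146 ± 55.2 CPM in PD against 71.1 ± 9.34 (log2 fold change 0.99 ± 0.23 SE, higher in 6 of 6). The glutamate receptor gene GRIN1 (1.28 ± 0.31, higher in 6 of 6) passed adjusted over the list alone (adjusted p = 0.0234), and ST6GALNAC5 (1.45 ± 0.37) and RAPGEF3 (1.05 ± 0.29) came next. Of 12543 genes, 234 had an unadjusted p under 0.05 (116 higher, 118 lower; 627 by chance), 151 without PD 4 and 375 without PD 6, and DESeq2 called 0. Of 33 lists, 10 were called. The hypoxia response lay higher (median 0.29, 24 members, camera adjusted p = 1.48e-05, 0.717 with an estimated correlation). ANKRD37, KDM3A, BNIP3L and BNIP3 were at 1.07, 0.55, 0.56 and 0.55. KDM3A and BNIP3 (higher in 3 of 6) were at 0.33 and 0.32 without PD 1, and BNIP3L at 0.31 without PD 4. The hypoxia median was 0.11 without PD 1 (adjusted p = 0.0863) and 0.45 and 0.51 without PD 2 and PD 5. Cholesterol synthesis lay lower (median -0.30, 22 of 23 members, camera adjusted p = 0.000170, 0.839 with an estimated correlation). It was at -0.16 without control 2 (adjusted p = 0.112) and -0.18 without PD 1 (adjusted p = 0.117). ACAT2 (-0.92 ± 0.38) and IDI1 (-0.65 ± 0.29) were lower in 6 of 6, with MSMO1 at -0.75. Without control 2, ACAT2, IDI1 and MSMO1 were at -0.55, -0.39 and -0.44. Proteasome genes (median -0.19, 29 of 34 lower) had a camera adjusted p of 0.00174 (0.839 with an estimated correlation) and kept the call without each library, at -0.11 and -0.12 without control 4 and PD 4. PSMA4, PSMA5, PSMA7 and PSMB5 were at -0.54, -0.46, -0.29 and -0.30. PSMB5 was at -0.17 without PD 4. Postsynaptic genes (median 0.13, camera adjusted p = 0.00248, 0.717 with an estimated correlation) lost it without control 4 (0.10, adjusted p = 0.0768) and PD 5 (0.13, adjusted p = 0.117), and were at 0.22 and 0.07 without control 1 and control 3. DLGAP2 and CAMK2A were at 0.54 and 0.43. They were at 0.35 and 0.19 without PD 5, and CAMK2A, higher in 3 of 6, at 0.28 without PD 2. Neuron-enriched genes outside the lists had a median of 0.34 in OPC-like nuclei, against 0.13 for members of the synaptic and channel lists and -0.03 for other genes.

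In excitatory neuron-like nuclei, DOCK11 was at 12.9 ± 2.24 CPM in PD against 7.62 ± 1.56 (log2 fold change 0.76 ± 0.22 SE, higher in 6 of 6), and MICB (-1.71 ± 0.52), SERPINH1 (-4.10 ± 1.29) and C5orf17 (2.70 ± 0.86; 0.60 without PD 5) came next. Of 18869 genes, 348 had an unadjusted p under 0.05 (140 higher, 208 lower; 943 by chance), 526 without PD 5, and DESeq2 called 0. Of 35 lists, 9 were called. Heat shock proteins and chaperones lay lower (median -0.30, 34 of 39 members, camera adjusted p = 6.35e-05, 0.841 with an estimated correlation). SERPINH1, BAG3, HSPD1 and HSPE1 were at -4.10, -3.34, -1.84 and -3.35. Without control 3, SERPINH1 and HSPD1 were at -0.19 and -0.07, and HSPE1, lower in 2 of 6 PD libraries, fell below the filter on counts. The heat shock call rested on control 3: without it the median was 0.03 (adjusted p = 0.450), against -0.46, -0.19 and -0.47 without control 1, PD 2 and PD 3, and only 1 of 6 PD libraries lay below the control median of BAG3, which was at 0.29 without control 3. Ribosomal proteins (median 0.14, 65 members, camera adjusted p = 0.00541, 0.860 with an estimated correlation) lost the call without control 1 (-0.01, adjusted p = 0.850), control 4 (0.08, 0.0728), PD 3 (-0.14, 0.0962) and PD 4 (0.08, 0.0765), and were at 0.30, 0.32 and 0.25 without PD 1, PD 5 and control 5. RPL35, RPL38 and RPL19 were at 1.504, 1.30 and 1.29. Each was higher in 3 of 6 PD libraries, and at 0.06, 0.06 and -0.07 without PD 3.

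Metallothioneins in excitatory neuron-like nuclei (median 0.64, 6 of 6 higher, camera adjusted p = 0.00564, 0.717 with an estimated correlation) lost the call without control 1 (0.01, adjusted p = 0.444) and PD 4 (0.25, adjusted p = 0.0639), and were at 0.37 without PD 1. MT1G, MT1M, MT1E and MT3 were at 1.30, 1.16, 0.80 and 0.54. MT1G, higher in 2 of 6 PD libraries, was at -0.23 without PD 4, MT1M at 0.51 and MT1E at 0.34. MT1M was at 1.89 without control 4, and MT3, higher in 3 of 6, at 0.13 without PD 3. Inhibitory neuron markers (median 0.11, 13 members, camera adjusted p = 0.0143, 0.839 with an estimated correlation) lost it without control 2 (adjusted p = 0.112), control 4 (0.134), PD 1 (0.123), PD 4 (0.07, adjusted p = 0.0955) and PD 5 (0.05, adjusted p = 0.523). ERBB4, GAD1, RELN and ADARB2 were at 0.72, 0.62, 0.52 and 0.53. Without PD 4, PD 5, PD 1 and control 3 in turn, they were at 0.36, 0.41, 0.34 and 0.93. The median of these markers was 0.43, 0.22 and 0.18 without control 3, control 5 and control 6, and 0.36, 0.35 and 0.20 without PD 2, PD 3 and PD 6.

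In inhibitory neuron-like nuclei, the fructose transporter gene SLC2A5 was at 2.35 ± 0.636 CPM in PD against 1.01 ± 0.383 (log2 fold change 1.17 ± 0.32 SE, higher in 6 of 6). SLC2A5 was also a top gene of a microglia-like cluster of 77 nuclei, and microglial RNA as the source of this low level was not tested. ZNF300 (-0.96 ± 0.28) and ZPLD1 (-1.23 ± 0.37) came next, while JUNB (4.49 ± 1.32; 1.68 without PD 3) lay above the control median in only 2 of 6 PD libraries. Of 16189 genes, 307 had an unadjusted p under 0.05 (161 higher, 146 lower; 809 by chance), 735 without PD 5, and DESeq2 called 0. Of 34 lists, 6 were called, all higher. The hypoxia response (median 0.24, 23 members, camera adjusted p = 1.33e-05, 0.717 with an estimated correlation) and microglia markers (median 0.47, 9 members, camera adjusted p = 0.000166, 0.717 with an estimated correlation) kept their calls without each library. ANKRD37, SLC2A3, SLC2A1 and LDHA were at 1.20, 1.00, 0.55 and 0.70. Without PD 3, ANKRD37, SLC2A3 and LDHA were at 0.56, 0.13 and 0.21. CD74, DOCK8, C3 and APBB1IP were at 1.14, 0.48, 0.76 and 0.50. CD74 was at 0.76 without PD 1, C3 at 1.17 without control 3 and APBB1IP at 0.32 without control 6. The list medians were 0.12 without PD 1 (hypoxia), and 0.12 and 0.30 without control 2 and control 4 (microglia markers). Here too, microglial RNA or nuclei were not tested apart from a change within inhibitory neurons. Oxidative phosphorylation genes (median 0.15, 54 of 57 higher, camera adjusted p = 8.44e-05, 0.841 with an estimated correlation) were at -0.01 without PD 3 (adjusted p = 0.977), and at 0.24, 0.23, 0.09 and 0.24 without PD 1, PD 5, PD 6 and control 5. NDUFA13, NDUFC1, ATP5ME and COX6B1 were at 2.15, 1.08, 1.19 and 1.18. They were at 1.09, 0.29, 0.25 and 0.34 without PD 3, and COX6B1 was higher in 2 of 6 PD libraries. Excitatory markers (median 0.17, 12 members, camera adjusted p = 0.0151, 0.717 with an estimated correlation) lost the call without PD 5 (-0.00, adjusted p = 0.262), and were at 0.10, 0.08 and 0.07 without control 2, PD 3 and control 6. SV2B, CAMK2A and SLC17A7 were at 0.56, 0.80 and 0.53. CAMK2A was higher in 2 of 6 PD libraries, and at 0.10 without PD 3.

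In vascular-like nuclei, tested in 5 PD and 5 control libraries, the transcriptional regulator gene ID3 was at 190 ± 74.2 CPM in PD against 508 ± 82.4 (log2 fold change -1.41 ± 0.30 SE, lower in 5 of 5). DESeq2 called 16 genes: ID3 (adjusted p = 0.00272; 0.00272 to 0.994 over the alternatives), KLF3 (-1.33 ± 0.31), PALMD, CMTM8, THSD7A, MAOA and PREX2 lower, and SIK2 (1.11 ± 0.27), RNF144A (1.60 ± 0.38), PLA2R1, IQCJ-SCHIP1, PRKAG2, RALYL, JAM3, SIPA1L1 and ADAMTSL3 higher. These 16, the 2 in astrocyte-like nuclei and 1 each in microglia-like and oligodendrocyte-like nuclei were chosen after their values were seen. The vascular-like class pools a cluster of 266 nuclei with COL1A2 and EBF1 among its top genes, and a cluster of 209 with CLDN5 and VWF. PD libraries gave 66.5% of the nuclei of the first and 45.0% of those of the second. For the genes and lists of this class, a difference in that mix was not tested apart from a change within either cluster. Of 3293 genes, 221 had an unadjusted p under 0.05 by edgeR (115 higher, 106 lower; 165 by chance). Of 27 lists, 5 were called. Antigen presentation (median -1.11, 6 of 6 lower, camera adjusted p = 0.000579, 0.717 with an estimated correlation) and interferon response (median -0.58, 14 of 14 lower, camera adjusted p = 0.00125, 0.738 with an estimated correlation) lay lower. HLA-B, B2M and HLA-E were at -1.30, -1.19 and -1.35. Without control 4 they were at -0.78, -0.78 and -0.89. IFI44, PARP14, XAF1 and EPSTI1 were at -1.28, -1.01, -0.65 and -0.82. PARP14 was at -0.43 without control 4, and EPSTI1 at -1.29 without PD 6. Oligodendrocyte markers (median 0.84, 9 of 9, camera adjusted p = 0.00172, 0.743 with an estimated correlation) lay higher. TF, CNP, ENPP2 and SLC44A1 were at 1.25, 0.91, 1.07 and 0.65. CNP was at 0.60 without control 3 and 0.54 without PD 6, and SLC44A1 at 0.42 without control 4 and 1.24 without control 6. These 3 kept their calls without each library. Interferon genes were at -0.38 without control 4 and -0.38 without PD 1, and oligodendrocyte markers at 0.54, 1.38 and 1.48 without control 4, PD 2 and control 6. Oxidative phosphorylation genes (median -0.39, 7 of 7 lower, camera adjusted p = 0.00800, 0.717 with an estimated correlation) lost the call without each of the 10 libraries (adjusted p between 0.0544 and 0.329). NDUFV2, NDUFS1 and ATP5F1E were at -1.01, -0.25 and -0.25. Without 1 library, NDUFS1 ran from -0.41 (PD 2) to -0.12 (PD 6) and ATP5F1E from -0.44 (PD 2) to -0.09 (PD 6).

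**Figure D2:**
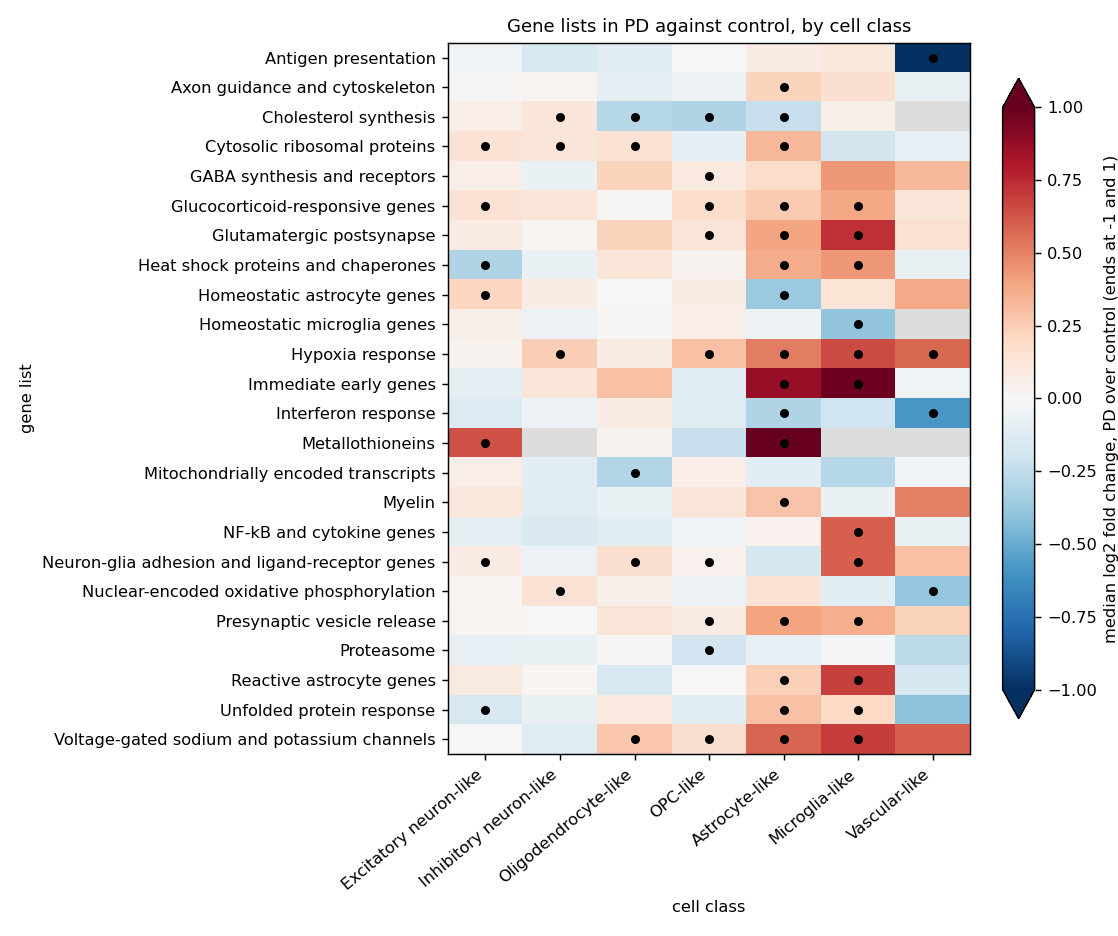
Median log2 fold change (PD over control) of the members of each gene list called in at least 1 class, by cell class; black dots mark camera calls at an adjusted p under 0.05, grey marks lists not tested, and the colour scale ends at -1 and 1. Hypoxia response medians are 0.51 in astrocyte-like and 0.65 in microglia-like nuclei.

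No movement of Parkinson's disease genes as a group was detected: the list of 38 genes was called in no class (smallest camera adjusted p = 0.191, in vascular-like nuclei; medians -0.03 to 0.20), and 0 members passed in any class. Of the genes read in the class of their highest level, LRRK2 in OPC-like (-0.07 ± 0.18 SE), PINK1 in excitatory neuron-like (-0.14 ± 0.29), PARK7 and MAPT in oligodendrocyte-like (-0.16 ± 0.22 and 0.28 ± 0.17) and VPS35 in microglia-like nuclei (0.18 ± 0.26) had an unadjusted edgeR p of at least 0.112. Without 1 library, LRRK2 ran from -0.17 (control 3) to -0.00 (PD 3), PINK1 from -0.32 (PD 3) to 0.01 (control 5), PARK7 from -0.26 (control 4) to -0.02 (control 5) and VPS35 from 0.07 (PD 6) to 0.41 (control 4). Lists of activated microglia, complement, and lysosome and autophagy genes, and the markers of astrocytes, T cells and vascular cells, were called in no class either (smallest camera adjusted p 0.0631, 0.175, 0.175, 0.0658, 0.137 and 0.183).

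Summed levels per library show which libraries carry the stress-related lists. In PD 3, immediate early genes summed to 10685 CPM in excitatory, 10130 in inhibitory, 3193 in oligodendrocyte, 2865 in OPC, 13176 in astrocyte and 12690 in microglia-like nuclei, above each other library. The next highest were 1552 (control 3), 1127 (PD 6), 732 (control 5), 1219 (control 4), 3004 (PD 6) and 3902 (PD 6). Heat shock genes summed to 14335 CPM in excitatory neuron-like nuclei of control 3, against 3890 in the next library. In microglia-like nuclei, they summed to between 3775 and 4976 CPM in 5 PD libraries, above the highest control (2837), and to 1667 in PD 5. On the log2 scale, the PD minus control difference was 1.502 for immediate early genes in astrocyte-like nuclei (exact permutation p = 0.0519) and 1.32 in microglia-like nuclei (exact p = 0.0563), and 0.87 and 0.84 without PD 3. For these genes in excitatory, inhibitory, oligodendrocyte and OPC-like nuclei it was 0.26, 0.80, 0.42 and 0.09. Without PD 3 those values were -0.44, 0.03, -0.02 and -0.35. The difference was 0.90 for heat shock genes in microglia-like nuclei (exact p = 0.0303). In excitatory neuron-like nuclei it was -0.39 (exact p = 0.615), and turned to 0.12 without control 3. It was -0.61 without control 1, -0.26 without PD 2 and -0.61 without PD 3. None of these 24 tests passed (smallest adjusted p = 0.416).

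**Figure D3:**
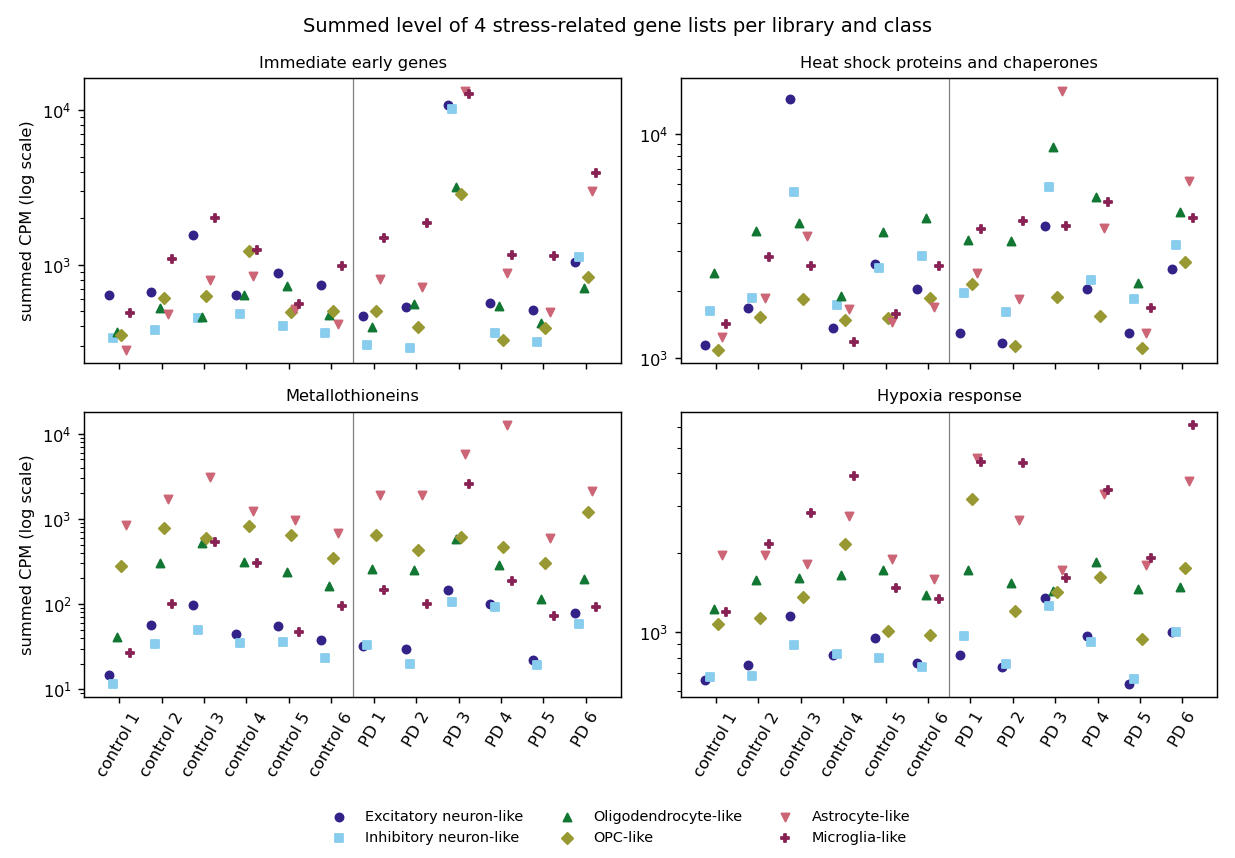
Summed level (CPM, log axis) of 4 gene lists in each library, with a symbol for each of 6 cell classes and a vertical line between control and PD libraries. PD 3 holds the highest immediate early level in all 6 classes, 13176 CPM in astrocyte-like nuclei.

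Fold changes correlated across genes between classes: over the 15 pairs of the 6 classes with 12 libraries, the median Pearson r was 0.336 (0.164 to 0.593) and the median Spearman rho 0.326. Genes are not independent replicates, and the same donors give every class. Of 100 splits of the donors, 42 gave a median r as high (median of the other splits 0.308), so a median this high is common among groupings of the same donors. For genes at 20 CPM or more the median r was 0.366, with 45 splits as high.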

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

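The tests of other splits, of class pairs, of free neuronal RNA and of a shared PD effect were chosen after the results they test had been seen; the test on nuclei with more UMIs was fixed before its result. Of 72 groups of libraries tested for a single distant library, 7 had one, and chance gives about 1 in 20 groups (3.6 of 72). Of the 7, 3 were in PD 3.

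Libraries far from the rest of their group were PD 3 for immediate early genes in excitatory neuron-like nuclei (10685 CPM) and in oligodendrocyte-like nuclei (3193 CPM; next PD library 704), and for metallothioneins in microglia-like nuclei (2596 CPM; next 185). Control 3 stood apart for heat shock genes in excitatory neuron-like nuclei (14335 CPM; next control 2633), and PD 5 for a low heat shock level in microglia-like nuclei (1667 CPM; next 3775). Among shares of nuclei, control 2 held 25.4% inhibitory neuron-like nuclei (next control 16.3%) and PD 1 held 19.1% microglia-like nuclei (next PD library 8.05%).

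Class pairs were tested for a difference in the PD effect only where a list had been called in opposite directions in both, so the pairs were picked on these data and their p values are too small to that extent. The score of a list is the mean log2 of CPM + 1 over its members. Heat shock genes passed. Relative to excitatory neuron-like nuclei, the PD minus control difference of the list score was higher by 0.82 in astrocyte-like nuclei (exact permutation p = 0.0108, adjusted p = 0.0433) and by 0.99 in microglia-like nuclei (exact p = 0.00216, the smallest possible, adjusted p = 0.0173). For the unfolded protein response the differences were 0.49 in astrocyte-like (exact p = 0.0281, adjusted p = 0.0563; 0.30 without PD 1, exact p = 0.0563) and 0.47 in microglia-like nuclei (exact p = 0.0195, adjusted p = 0.0519). Of the 8 class pairs tested, 4 had a p under 0.05 and 2 passed after adjustment. Without control 3 and PD 3, a choice made after seeing the data, the 4 differences were 0.48 (exact p = 0.0397), 0.75 (exact p = 0.00794), 0.42 (exact p = 0.103) and 0.52 (exact p = 0.00794, the smallest possible for 5 against 5 libraries). These p values were not adjusted for the 8 class pairs, so they do not show whether a pair would still pass. The excitatory heat shock median itself was 0.03 without control 3.

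Immediate early genes were high in all 6 classes of PD 3. The values argue against free neuronal RNA in its astrocyte-like and microglia-like nuclei, while its oligodendrocyte-like and OPC-like nuclei were not tested in this way. The level in the astrocyte-like nuclei, 13176 CPM, was 13.9 times the 947 CPM that the neuronal share of their RNA allows. In microglia-like nuclei the ratio was 32.9. The neuronal share is the level of neuron-enriched genes in a glial class, in percent of their level in excitatory neuron-like nuclei of the library. Such genes lie above 100 CPM in neurons and above 8 times their level in the glial class. The share also counts what glia express of these genes themselves. Nuclei of few UMIs are argued against in excitatory neuron-like, inhibitory neuron-like and microglia-like nuclei. There the PD 3 median UMIs per nucleus (11853, 7291.5 and 2796.5) lay within the range of the other libraries. The PD 3 nuclei at or above its class median stayed above the highest other library in 6 of 6 classes. In oligodendrocyte-like, OPC-like and astrocyte-like nuclei that median (2174, 891 and 1065) was the lowest of all libraries. Nuclei above it can still hold few UMIs, so the test cannot decide there. An effect of PD shared by the other PD donors cannot be told apart from none: without PD 3 the smallest exact permutation p was 0.104 (adjusted p = 0.338), and 5 against 6 libraries can miss a difference. A response before death or during tissue handling stays open and was not tested, in PD 3 or in PD 6, which was second highest and above each control in inhibitory neuron-like, astrocyte-like and microglia-like nuclei (1127, 3004 and 3902 CPM).

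Synaptic and ion channel lists lay higher in PD astrocyte-like and microglia-like nuclei, which may reflect free neuronal RNA, but no call held with an estimated correlation (adjusted p of 0.717 or more), and the astrocyte postsynaptic (adjusted p = 0.0953) and microglial presynaptic (0.190) and channel (0.0867) calls ended without PD 5, the presynaptic one also without control 6 (0.0551). In astrocyte-like nuclei, 301 neuron-enriched genes outside the lists had a median log2 fold change of 0.66, against 0.43 for list members and -0.01 for other genes, which is what free RNA predicts. In microglia-like nuclei the value was 0.64 (309 genes), against 0.73 for list members and 0.02 for other genes: below the members, so the test left the question open. The neuronal share of RNA was 5.68 ± 1.96% in PD against 4.05 ± 1.21% in controls in astrocyte-like nuclei (exact permutation p = 0.113, adjusted p = 0.450; difference 1.62, and 0.987 without PD 3) and 5.83 ± 3.97% against 4.26 ± 1.21% in microglia-like nuclei (exact p = 0.511), where PD 5 alone stood at 13.8% and the difference of 1.58 turned to -0.0143 without it. The splits were counted for the presynaptic, postsynaptic and channel lists, and the smallest count of the 3 is given. Of 100 splits, 9 gave a camera p as small in astrocyte-like nuclei (6.46e-07 in the real split, 1.53e-13 in the strongest other). In microglia-like nuclei 12 did (3.36e-07 and 3.85e-14), so chance is not excluded. A change within glia stays untested.

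The real split called 0 genes in each class, so the number of splits with as many (100 of 100) is fixed in advance and says nothing about chance. The highest other split called 1 gene in excitatory neuron-like, 4 in inhibitory neuron-like, 5 in oligodendrocyte-like, 193 in OPC-like, 81 in astrocyte-like, 0 in microglia-like and 2 in vascular-like nuclei. Splits calling 193 and 81 genes point to a structure of the samples, but only 8 and 6 of the other splits called any gene in OPC-like and astrocyte-like nuclei, and no test separated such a structure from chance. Chance could not be excluded for the other counts. At an unadjusted p under 0.05, as many genes came from 100 of 100 splits in excitatory neuron-like nuclei (348 in the real split; highest other 3298), 96 in inhibitory neuron-like (307; 2642), 72 in oligodendrocyte-like (455; 1734), 83 in OPC-like (234; 1831), 47 in astrocyte-like (537; 1751), 34 in microglia-like (528; 1126) and 18 in vascular-like nuclei (221; 407). The medians of the other splits were 1170, 724, 651, 443, 514, 431 and 134 genes, in the same order of classes. The counts by chance given with each class are 0.05 times the genes tested, not these medians. As many list calls as the 66 of the classes with 12 libraries came from 33 splits (highest other 110), and a median correlation between classes as high as 0.336 from 42 (highest other 0.486).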

How the results depend on the processing

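The mitochondrial block and leaving out control 3 and PD 3 together were chosen after seeing the data; the other alternatives were planned. Where no reason is given below, the cause was not tested. Genes called stayed at 0 under every alternative in excitatory neuron-like, inhibitory neuron-like and OPC-like nuclei. DESeq2 called 1 gene in oligodendrocyte-like, 2 in astrocyte-like, 1 in microglia-like and 16 in vascular-like nuclei, and edgeR without a filter on low counts 78 in vascular-like nuclei; without a library, edgeR called 0 to 1 in microglia-like nuclei. Gene lists called numbered 70, against 0 with an estimated correlation, which allows for members moving together, and 0 by fry, 73 with the depth covariate (55 shared), 93 with doublets kept (64 shared), 73 with the prefix block (69 shared), 68 with a surrogate variable (61 shared), 69 with the class from marker scores (65 shared), 76 with the mitochondrial block (62 shared), 81 without control 3 and PD 3 (58 shared), and 52 to 84 without each library. No test varied depth. In simulated data with the real library sizes, 59.1% of genes changed 4-fold were recovered in excitatory neuron-like nuclei, the class with the highest UMI sums. The values were 60.6% in vascular-like, the tested class with the fewest nuclei, 71.2% in microglia-like and 80.3% to 86.4% in the remaining classes. The classes also differ in tested genes and spread, so these values cannot show whether recovery follows depth.

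On the centred log ratio scale, the vascular share difference was -0.0232, and those of upper and deep layers 0.0788 and -0.253. Within the capitals spelling alone, differences turned to 1.38 for inhibitory neurons, 1.07 for astrocytes, -0.872 for microglia, -0.1797 for vascular and -0.0304 for T cell-like nuclei. The middle-layer difference was -0.100 with doublets kept. Without control 3 and PD 3, the upper and deep layers differed by 0.974 and -4.01. Without each library in turn, differences ranged from 384 to 1915 for kept nuclei, -974 to 167 for median UMIs, -0.128 to 0.0615 for the mitochondrial share, -1.70 to 1.23 for the inhibitory share, -3.98 to 2.54, -3.60 to 2.503 and -5.38 to 3.85 for upper, middle and deep layers, and -0.432 to 3.73 for SST nuclei.

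Of named lists and genes, those that turned did so as follows. With the depth covariate: ribosomal proteins -0.0207, homeostatic astrocyte genes 0.15, RPS9 -0.11 and RPL10 -0.0474 in astrocyte-like nuclei. Without control 3 and PD 3: ribosomal proteins -0.10 in excitatory, -0.11 in inhibitory (called in the opposite direction, adjusted p = 0.00174) and -0.00705 in oligodendrocyte-like nuclei, oxidative phosphorylation 0.00408 in inhibitory nuclei (the test's direction turned), BAG3 0.21, RPL19 -0.0665 and RPS28 -0.0332. In vascular-like nuclei, PARP14 and XAF1 were 0.0526 and 0.0724 with doublets kept, and SLC44A1 and ATP5F1E -0.0384 and 0.25 with the class from marker scores. Ranges without each library that crossed 0 were -0.0244 to 0.52 for the astrocyte unfolded protein response, -0.23 to 0.73 for reactive astrocyte genes, -0.47 to 0.0253 and -0.28 to 0.00455 for excitatory heat shock and unfolded protein response, -0.14 to 0.32 and -0.0507 to 0.25 for excitatory and inhibitory ribosomal proteins, -0.0332 to 0.23 for inhibitory cholesterol synthesis, -0.0101 to 0.24 for inhibitory oxidative phosphorylation, -0.00105 to 0.26 for excitatory markers in inhibitory nuclei, -0.0216 to 0.17 and -0.0199 to 0.22 for OPC and oligodendrocyte adhesion genes, -0.42 to 0.0144 for oligodendrocyte mitochondrial transcripts, -0.0719 to 0.37 for OPC glucocorticoid genes, -0.32 to 0.0124 for PINK1, -3.59 to 0.29 for BAG3, -0.0745 to 1.51 for RPL19, -0.23 to 1.56 for MT1G, -0.26 to 4.09 for HOMER1 and -0.0388 to 1.07 for RPS28. In all, 3182 values of named genes kept direction and side of the threshold, against 15 turned and 8 newly past it; for lists, 1088 kept both, 220 lost the call and 12 turned in the direction of the test.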

Other observations

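The hopping test was written before its result was seen. Mitochondrial shares of UMIs were 0.713, 0.379, 0.352, 0.347, 0.807 and 0.667% in controls 1 to 6 and 0.311, 0.390, 0.264, 0.319, 0.796 and 1.21% in PD 1 to 6, the highest being in PD 6.

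Some clusters came largely from 1 library. Excitatory neuron clusters of 197, 78 and 26 nuclei drew 86.3, 100 and 100% of their nuclei from control 3. HSPA6 and DNAJB1 were among the top genes of the cluster of 197, and HSPH1 among those of the cluster of 78. The cluster of 26 had no heat shock gene among its top 10. A microglia-like cluster of 77 nuclei with IL1B and THBD among its top genes drew 94.8% from 1 library, and 97.4% of its nuclei were from PD libraries. An excitatory cluster of 732 nuclei drew 66.4% from 1 library.

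Barcodes shared between PD 3 and other libraries may come from index hopping, in which reads of a library are assigned to another on the same run. PD 3 shared 45 barcodes with PD 4 (2.38% of its own) and 37 with control 6 (1.96%), against a median of 0.224% over the pairs without PD 3. Of 91 shared barcodes with a UMI ratio of at least 20 in pairs with PD 3, the large copy was the best match of the small one among 200 nuclei of its library in 98.9%, against 0.5% by chance and 59.3% of 27 in other pairs. The median UMIs were 617 in the small copies and 38894 in the large ones, and 46.2% of the copies were named as the same class. With control 6, 33 of 34 small copies lay in PD 3, but with PD 4 only 2 of 35 did, so the large copy was mostly in PD 3, the smallest library. PD 3 held 54 small copies (2.86% of its barcodes), and 62 were kept over all libraries, so few of all nuclei are concerned. The small copies were not counted per class. PD 3 held only 59 OPC-like and 55 astrocyte-like nuclei, so their share in those classes of PD 3 is not known.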
